A study of Mus musculus with 6 samples.

How the data were processed

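RNA was measured in eYFP-positive cells sorted by flow cytometry from fetal livers of CD-1 mice that carried Cre under the Sm22 (Tagln) promoter and a Cre-dependent eYFP reporter, per the labels. The labels give 3 libraries at embryonic day 16 (E16) and 3 at embryonic day 18 (E18), each set lettered A, B and C. They do not say whether the 3 libraries of a day came from separate litters or pools, so p-values measure the spread between these libraries, which may be partly technical. Per the labels' protocols, total RNA was made into libraries with a stranded total RNA kit.

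The deposited table holds TPM (length-normalized transcript abundance with a fixed library total) for 54532 genes in 6 columns, made by the authors. The submitters' processing notes name the mm10 build, FastQC 0.11.7, HISAT2 2.1.0, Bowtie and HTSeq 0.5.4p3, without role or order. The strand setting of the counting, the annotation release and the TPM formula are not given in the sources used here. Genes were named through a table of Ensembl identifiers and symbols, which covered 54409 identifiers and left 123 without a name. Positions, gene types and exon lengths came from GENCODE M21 on GRCm38, the same assembly as mm10, and are counted from 1. Genes listed at 0 in all 6 libraries numbered 25316.

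TPM does not state depth. Multiplied by the summed length of a gene's merged exons, however, 96.8% to 97.1% of the values above 0 in each library were whole multiples of 1 step within 0.05 of a read. Read totals recovered in this way were 22626879, 21580361 and 21130205 at E16 and 14587555, 15613418 and 18281952 at E18. A gene of 1 kb at 1 TPM then rests on 4.41 to 6.83 reads, so values near 1 TPM are coarse. Pairs of replicates differed by 20.9 to 107 times the sampling noise (chi-square per degree of freedom on recovered reads), so no pair looks like repeat deposits of 1 library; this does not show that the libraries came from separate animals.

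Genes with TPM of at least 1 in at least 3 of the 6 libraries were tested, 17824 in all. E18 was compared with E16 by limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with an intensity trend, empirical Bayes moderation and 2-sided p-values adjusted by Benjamini-Hochberg over the genes tested. Genes at adjusted p under 0.05 were called. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Exact permutation of 3 against 3 libraries cannot give p below 0.1.

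Before the data were examined, 36 gene lists by symbol and 3 by name pattern were fixed, together with the tests, most of the alternatives and the rule for naming genes. Of all listed genes, 1 was unmatched. Lists with at least 5 tested members, 34 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists; camera with an estimated correlation, camera on ranks and fry were run beside it. Calls of members were counted over all genes and adjusted over the list alone. The naming rule took, among called genes whose 3 E18 values all lay above or all below the 3 E16 values and whose mean was at least 10 TPM on the higher day, the 10 with the largest rise and the 10 with the largest fall; up to 4 tested members of each list with the smallest p; and 15 fixed genes. Predicted gene models, 89 of the calls, were counted and not named. 1 gene that the rule takes is not reported here. Ahsg was named after its values were seen.

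The steps were tested on 5 simulated data sets with the means and residual spreads of the 17824 genes and 200 changed genes each, for the E18 against E16 comparison. The fit recovered 15.2% of 2-fold changes, 57.3% of 4-fold changes and 77.3% of 8-fold changes, and 4.78% of its calls were false. Camera called the shifted list in 5 of 5 data sets and 1 of 95 unshifted lists of independent genes. All simulated genes varied independently. In the real lists the estimated inter-gene correlation ran from 0.0115 (megakaryocyte) to 0.943 (interstitial collagen), so these error rates need not hold for the real data.

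Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, other filters, median-of-ratios and quantile scaling, rescaling without hepatocyte and erythroid lists or without mitochondrial and small RNA genes, no intensity trend, array weights, a hepatocyte score as covariate, the letter as a block, a minimum fold of 1.5 and leaving out each library. Alternatives added after seeing the data were limma's voom on recovered reads, reads thinned to 14587555 per library, a collagen score as covariate, leaving out both B libraries, and leaving the gene Gm26917 out of the rescaling. Figures were drawn with Matplotlib 3.10.9.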

Results

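Gene expression was measured in eYFP-positive cells sorted from fetal liver at 2 stages of late gestation. There were 3 libraries at embryonic day 16 (E16) and 3 at embryonic day 18 (E18). Sorted cells carried the eYFP mark left by Cre expressed from the Sm22 promoter, which is active in smooth muscle and related mesenchyme. The libraries also held erythroid and hepatocyte transcripts. Mean summed TPM at E16 and E18 was 9650 and 20707 for the erythroid list and 5135 and 843 for the hepatocyte core list. For the smooth muscle contractile list it was 104 and 510. These sums do not measure cell shares, and differences between the days cannot be assigned to mesenchymal cells alone. Recovered depth was 21779148 ± 767884 reads at E16 and 16160975 ± 1907094 at E18 (mean ± SD, n = 3 each), higher in every E16 library than in any E18 library. A single gene, Gm26917, took 26.2% ± 7.13 of TPM at E16 and 24.6% ± 1.78 at E18 (SD, n = 3), and the 2 mitochondrial ribosomal RNAs took 11.7% ± 0.880 and 10.3% ± 0.841. Protein-coding genes held 44.6% to 59.2% of TPM.

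On average, libraries of the same day resembled each other more than libraries of different days. The mean Pearson correlation of log2(TPM + 1) was 0.920 over 6 pairs within a day and 0.875 over 9 pairs between days (Spearman 0.913 and 0.864). The Pearson ranges overlapped, at 0.893 to 0.942 within a day and 0.821 to 0.909 between days. E18 replicate C correlated at 0.909 with E16 replicate C and 0.904 with E16 replicate B, against 0.893 with E18 replicate B and 0.922 with E18 replicate A. The first principal component held 46.8% of the variance and separated the days, with E16 libraries from −70.1 to −36.4 and E18 libraries from 15.8 to 90.0. Its extremes were E16 replicate B and E18 replicate B.

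The comparison of E18 with E16 asked which transcripts of the sorted samples differ between these stages. Genes of the extracellular matrix and of smooth muscle were higher at E18, and genes of hepatocytes were lower. Elastin (Eln, chromosome 5, 134702593 to 134747323, mm10) rose from 8.02 ± 2.37 to 170 ± 86.1 TPM (SD, n = 3 each), a log2 fold change of 4.17 ± 0.36 (SE; limma adjusted p = 0.0153). Corticosteroid-binding globulin (Serpina6, chromosome 12, 103646630 to 103657212) fell from 118 ± 72.5 to 1.39 ± 2.18 TPM, a log2 fold change of −5.85 ± 0.66 (limma adjusted p = 0.0273). Serpina6 was at 0.129, 0.124 and 3.91 TPM in E18 replicates A, B and C, so replicate C raises its E18 mean. In all, limma called 618 of 17824 genes, 549 higher and 69 lower at E18. Each of the 618 had non-overlapping values on the 2 days. With 3 libraries a day a gene with overlapping values can hardly be called, so this adds no separate support. Over all tested genes 26.5% had non-overlapping values, against 10% by chance. Genes vary together, so these shares are not a test. The higher share of calls, 88.8%, was 78.7% with quantile normalization, which moved the median log2 fold change of all genes from 0.07 to −0.08, 76.5% when Gm26917, mitochondrial and small RNA genes were left out of the scaling, and 64.8% with array weights. The call count changed when single libraries were left out. It was 0 without E16 replicate A, E16 replicate C, E18 replicate A or E18 replicate B. It was 55 without E16 replicate B and 664 without E18 replicate C. In these fits log2 fold changes correlated at 0.943 to 0.968 with those from all 6 libraries, and none of the 618 genes changed sign. The call count was also 0 without a filter on low values or with the hepatocyte score as covariate, 18 at a minimum fold of 1.5, and 4316 with array weights.

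**Figure D1:**
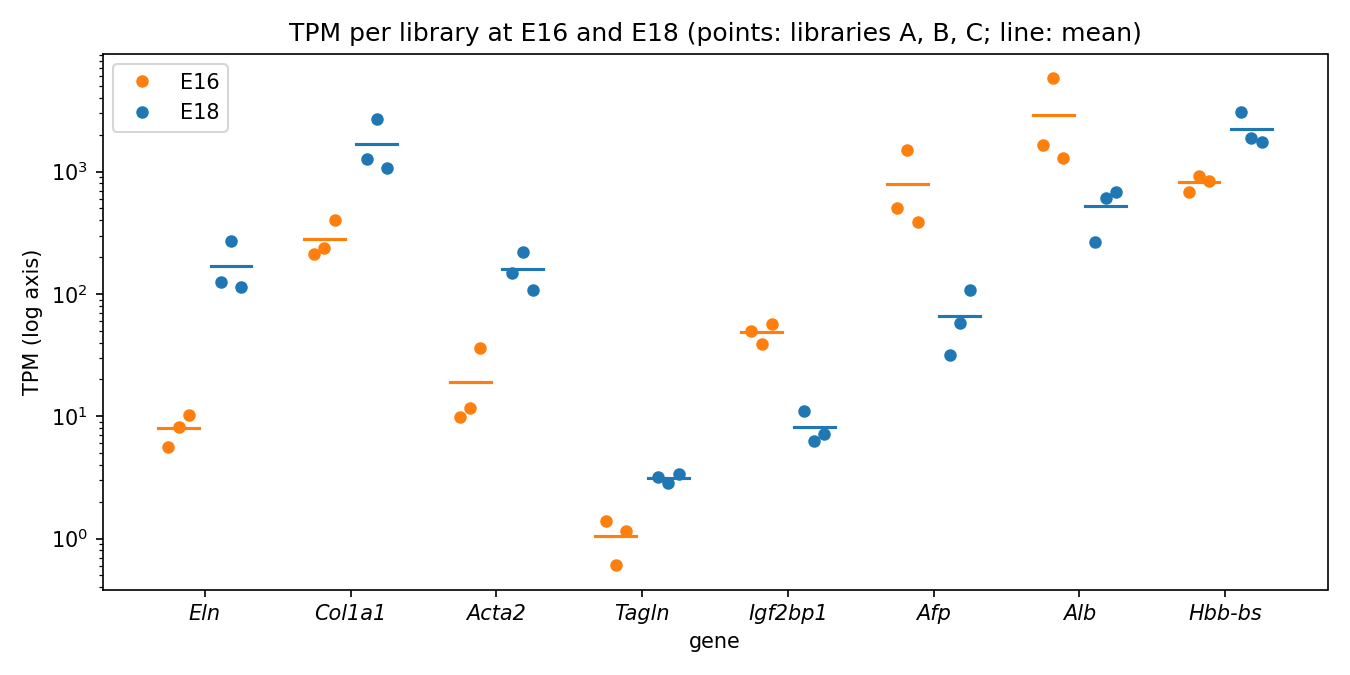
TPM on a log axis for 8 named genes, with 1 point per library at E16 and E18 (n = 3 each) and a line at each mean. Eln, Col1a1 and Acta2 lie higher at E18 in all 3 libraries, Igf2bp1, Afp and Alb lie lower, and Tagln reaches at most 3.37 TPM.

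Among the largest rises after Eln were those of Ltbp2 (4.15 ± 0.40, log2 ± SE), Mgp, an inhibitor of matrix calcification (4.01 ± 0.38), Dpt, a matrix protein that binds decorin (3.75 ± 0.32), and Adamtsl2 (3.70 ± 0.49). Egln3, an oxygen-sensing prolyl hydroxylase, rose by 3.56 ± 0.42. Ifitm3 (3.50 ± 0.50), the netrin receptor Unc5b (3.48 ± 0.51) and Arhgef3 (3.48 ± 0.48) followed. Limma adjusted p for these 9 genes, Eln included, lay between 0.0153 and 0.0314. Each was higher in 3 of 3 E18 libraries than in any E16 library, which the naming rule requires. Arhgef3 went from 6.80 ± 6.06 to 71.1 ± 5.57 TPM (SD, n = 3), with 3.95, 13.8 and 2.70 TPM in E16 replicates A, B and C.

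The interstitial collagen list rose as a whole: 12 of 12 tested members were called, and the median log2 fold change was 2.52. Col1a1 went from 282 ± 102 to 1683 ± 881 TPM (2.51 ± 0.40 on the log2 scale; limma adjusted p = 0.0333) and Col3a1 from 102 ± 32.8 to 725 ± 474 TPM (limma adjusted p = 0.0351). The summed TPM of the list was 477, 588 and 870 in E16 replicates A, B and C and 3080, 6549 and 2567 in E18 replicates A, B and C, so E18 replicate B raises these means and their spread; Col3a1 was at 510, 1268 and 396 TPM in E18 replicates A, B and C. Col6a1 and Col6a3, chains of the beaded-filament collagen VI, rose by 2.82 ± 0.33 and 3.16 ± 0.41. Among 23 elastic fibre and proteoglycan genes 17 rose, with a median of 2.50, Bgn at 3.25 ± 0.45 and Fbln1 at 2.77 ± 0.38. In the collagen processing and matrix remodelling list 14 of 25 rose, among them the gelatinase Mmp2 (3.29 ± 0.39) and Postn (2.82 ± 0.36). In the basement membrane list 11 of 18 rose, among them Col4a2 (3.04 ± 0.44) and Lama2 (3.08 ± 0.47). Adjusted over the list alone, the calls were 12, 23, 23 and 17. Camera adjusted p values were 2.9e-13, 1.4e-17, 2.8e-14 and 5.3e-12; each was 0.314 with an estimated correlation.

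Markers of mesenchymal cell types were higher together. In the smooth muscle contractile list 9 of 13 members rose (13 adjusted over the list alone), with Actg2 going from 3.68 ± 0.994 to 47.1 ± 14.9 TPM, Acta2 from 19.2 ± 14.5 to 159 ± 55.7 TPM and Myh11 from 1.67 ± 0.681 to 24.5 ± 12.2 TPM (SD, n = 3). Tagln, whose promoter drove the Cre, stood at 1.06 ± 0.408 and 3.14 ± 0.258 TPM (limma adjusted p = 0.111), and 67.9% of its exon length lies under exons of genes on the opposite strand. In the portal fibroblast list 11 of 14 rose (13 adjusted over the list alone), with Cd34 at 2.61 ± 0.34. In the hepatic stellate cell list 4 of 18 rose (16 adjusted over the list alone): Cygb by 3.09 ± 0.49, Rgs5 by 2.88 ± 0.41, Pdgfrb by 2.62 ± 0.49 and the intermediate filament gene Des by 2.94 ± 0.61, the last at limma adjusted p = 0.0499. The summed TPM of the stellate list was 59.9, 83.4 and 106 in E16 replicates A, B and C and 228, 599 and 203 in E18 replicates A, B and C, highest in E18 replicate B. Mesothelial Msln rose by 2.73 ± 0.27 and Upk3b by 1.54 ± 0.26, 3 of 13 in that list (10 higher and 2 lower adjusted over the list alone). Of 20 mesenchymal transcription factors 3 rose (17 higher and 1 lower adjusted over the list alone), among them Tcf21, a regulator of visceral mesenchyme (2.99 ± 0.53), and Myocd, a co-activator of smooth muscle genes (0.204 ± 0.0843 to 4.42 ± 1.98 TPM). Camera adjusted p for these 5 lists was 1.7e-11, 1.1e-12, 2.7e-08, 0.00101 and 2.0e-08, and 0.314 for each with an estimated correlation.

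Signalling genes rose in several lists. Of 29 TGF-beta and BMP genes 11 rose (23 higher and 1 lower adjusted over the list alone), including Bmp4 (2.17 ± 0.30) and Ltbp3 (2.70 ± 0.40), and of 22 axon guidance genes 7 rose (19 adjusted over the list alone), including Slit3 (2.05 ± 0.34) and Epha4 (2.31 ± 0.39). Of 18 Wnt and R-spondin genes 6 rose (9 adjusted over the list alone), including the Wnt antagonists Dkk3 (2.58 ± 0.30) and Sfrp1 (3.27 ± 0.56), and of 9 Hedgehog genes 3 rose (7 adjusted over the list alone), including the co-receptor Boc (3.18 ± 0.37) and Gli2 (2.24 ± 0.43). Of 16 genes of PDGF, VEGF and angiopoietin signalling 3 rose (10 adjusted over the list alone), including Pdgfra (2.78 ± 0.44) and Vegfd (2.78 ± 0.40). Of 11 growth factor genes Cxcl12, a chemokine that holds blood stem cells (2.72 ± 0.47), and Igf1 (1.91 ± 0.34) rose (7 adjusted over the list alone). Notch3 rose by 2.60 ± 0.43, the called member among 11 Notch genes (6 adjusted over the list alone), while the Notch ligand Jag1, with 6.01 ± 3.89 and 23.4 ± 12.6 TPM, did not pass (limma adjusted p = 0.0805). In the retinoid list of 12, Aldh1a1 rose by 2.03 ± 0.27 and Rbp4 fell by 3.08 on the log2 scale (7 higher and 1 lower adjusted over the list alone). Camera adjusted p ran from 5.3e-12 (TGF-beta and BMP) to 0.0398 (retinoid handling); with an estimated correlation these 8 lists lay between 0.314 and 0.473 in adjusted p.

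Immediate early and heat shock genes, which respond to tissue dissociation among other stimuli, were also higher: 8 of 26 rose (20 higher and 1 lower adjusted over the list alone), with Ccn2 at 3.20 ± 0.39, the nuclear receptor Nr4a1 at 3.35 ± 0.47 and Klf4 at 3.05 ± 0.47. In the interferon and MHC class I list 2 of 17 rose, Ifitm3 and Ifitm1 (3.41 ± 0.47), and 10 did adjusted over the list alone. Camera adjusted p was 2.2e-09 and 1.0e-06, and 0.314 for both with an estimated correlation. The hypoxia and glycolysis list, with Egln3 and Ndrg1 (1.99 ± 0.37) called among 18, did not pass (camera adjusted p = 0.50); 2 members passed adjusted over the list alone.

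Hepatocyte transcripts were lower at E18. Of 23 hepatocyte core genes 7 fell (19 adjusted over the list alone), the median log2 fold change was −2.26 and the camera adjusted p 7.2e-18, or 0.314 adjusted p with an estimated correlation. Alpha-fetoprotein (Afp) fell from 797 ± 611 to 66.2 ± 39.1 TPM (limma adjusted p = 0.0359). Hpx fell by 3.30, Apob by 3.13, Itih2 by 3.06 and Apoa1 by 2.78 on the log2 scale, and outside the list Serpinf2 fell by 3.08 and the gap junction gene Gjb2 by 3.10. Lect2 was at 10.5 ± 6.25 TPM at E16 and is listed at 0 in each E18 library. Albumin (Alb) was at 2909 ± 2498 and 521 ± 223 TPM and did not pass (limma adjusted p = 0.0903). The summed TPM of the hepatocyte core was 3007, 9994 and 2406 in E16 replicates A, B and C and 434, 968 and 1128 in E18 replicates A, B and C. Among 11 late fetal hepatocyte genes none was called over all genes (1 higher and 6 lower adjusted over the list alone), and the urea cycle gene Ass1 was at 61.5 ± 33.5 and 19 ± 4.63 TPM. That list's camera adjusted p was 0.000826, and 0.349 with an estimated correlation.

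Erythroid transcripts were abundant in every library, with a summed TPM over the erythroid list of 9650 ± 1324 at E16 and 20707 ± 4734 at E18 (SD, n = 3). Of 21 erythroid genes 2 rose, the membrane skeleton gene Sptb (0.93 ± 0.14) and the alpha globin gene Hba-a2 (1.63 ± 0.33), and 16 rose and 1 fell adjusted over the list alone (camera adjusted p = 5.6e-07, or 0.314 adjusted p with an estimated correlation). Hba-a2 has a near-identical copy, so its value is uncertain. Adult beta globin (Hbb-bs) was at 818 ± 125 and 2226 ± 721 TPM (limma adjusted p = 0.0503).

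Of the other blood and endothelial lists, only the neutrophil list held genes called over all genes. Ptprc, the pan-leukocyte marker, stayed at 0.0613 ± 0.0712 and 0.0331 ± 0.0304 TPM and the endothelial gene Pecam1 at 0.487 ± 0.353 and 0.839 ± 0.361 TPM (SD, n = 3), under the filter. Of the macrophage, B lymphoid, embryonic globin, mast cell and cardiac or skeletal muscle lists, 3, 0, 0, 1 and 3 members passed the filter, none was called over all genes, 3 muscle genes were higher adjusted over the list alone, and the macrophage list reached 108 TPM through Cd68. The summed TPM of the megakaryocyte list was 57.7 ± 29.0 at E16 and 103 ± 46.9 at E18, and that of the endothelial list 47.6 ± 8.73 and 46.6 ± 10.03. Of 5 neutrophil genes Retnlg and S100a9 rose (4 adjusted over the list alone); both are listed at 0 in the E16 libraries and stood at 3.13 ± 0.827 and 4.43 ± 3.11 TPM at E18 (camera adjusted p = 0.00190, or 0.314 adjusted p with an estimated correlation). Of 15 cholangiocyte genes 6 passed the filter, and of these Krt19 was called, rising by 1.78 ± 0.29. Adjusted over the list alone, 4 were higher and 1 lower. The lower gene was Cdh1, at 7.34 ± 5.02 TPM at E16 and 0.692 ± 0.415 TPM at E18. That list's camera adjusted p was 0.0325, or 0.343 adjusted p with an estimated correlation. The endothelial list of 5, with Egfl7 at 34.3 ± 7.08 and 16.9 ± 5.14 TPM, and the megakaryocyte, Schwann cell, and complement and chemokine lists did not pass (camera adjusted p of 0.899, 0.10, 0.192 and 0.10). Adjusted over the list alone, 1 endothelial gene was higher and 1 lower, 1 complement and chemokine gene was higher, and 0 were called in the others.

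No direction was established for proliferation genes. Of 35 cell cycle genes none was called over all genes and 0 adjusted over the list alone, and the list's camera adjusted p was 0.102. The median log2 fold change was 0.14, against 0.07 over all genes, with 30 positive folds and 5 negative ones, and 22.9% of members had non-overlapping values on the 2 days (8 higher and 0 lower), against 26.5% of all tested genes. The members with the smallest p included Nusap1, Ube2c and Top2a. Mki67 was at 546 ± 81.3 and 845 ± 196 TPM (limma adjusted p = 0.187), Top2a at 174 ± 19.8 and 225 ± 4.35, Ube2c at 29.1 ± 4.58 and 40.7 ± 1.19 and Nusap1 at 42.9 ± 12.3 and 68.6 ± 6.16 TPM (limma adjusted p = 0.154, 0.124 and 0.119). Histone genes had a median log2 fold change of 0.34 and none of 69 called (camera adjusted p = 8.3e-05, or 0.477 adjusted p with an estimated correlation). Ribosomal protein genes had a median of −0.19 and none of 83 called, with Rps12 at 195 ± 9.68 and 131 ± 11.2 TPM (camera adjusted p = 5.6e-07, or 0.463 adjusted p with an estimated correlation). Mitochondrially encoded genes had a median of −0.28 and none of 16 called (camera adjusted p = 0.00843, or 0.352 adjusted p with an estimated correlation).

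Fetal growth and imprinted genes went both ways. The RNA-binding protein genes Igf2bp1 and Lin28b, which mark fetal stages, fell by 2.45 and 1.20 on the log2 scale, Igf2bp1 from 48.6 ± 8.90 to 8.20 ± 2.52 TPM (SD, n = 3; limma adjusted p = 0.0194). Of the 3 that rose, Meg3 rose by 1.74 ± 0.29 and Cdkn1c, an inhibitor of the cell cycle, by 1.44 ± 0.25. The list of 18 did not pass (camera adjusted p = 0.141), and 9 rose and 4 fell adjusted over the list alone. Igf2 was at 1.95 ± 0.785 and 3.26 ± 1.36 TPM (limma adjusted p = 0.521), and 64.5% of its exon length lies under exons of other genes.

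**Figure D2:**
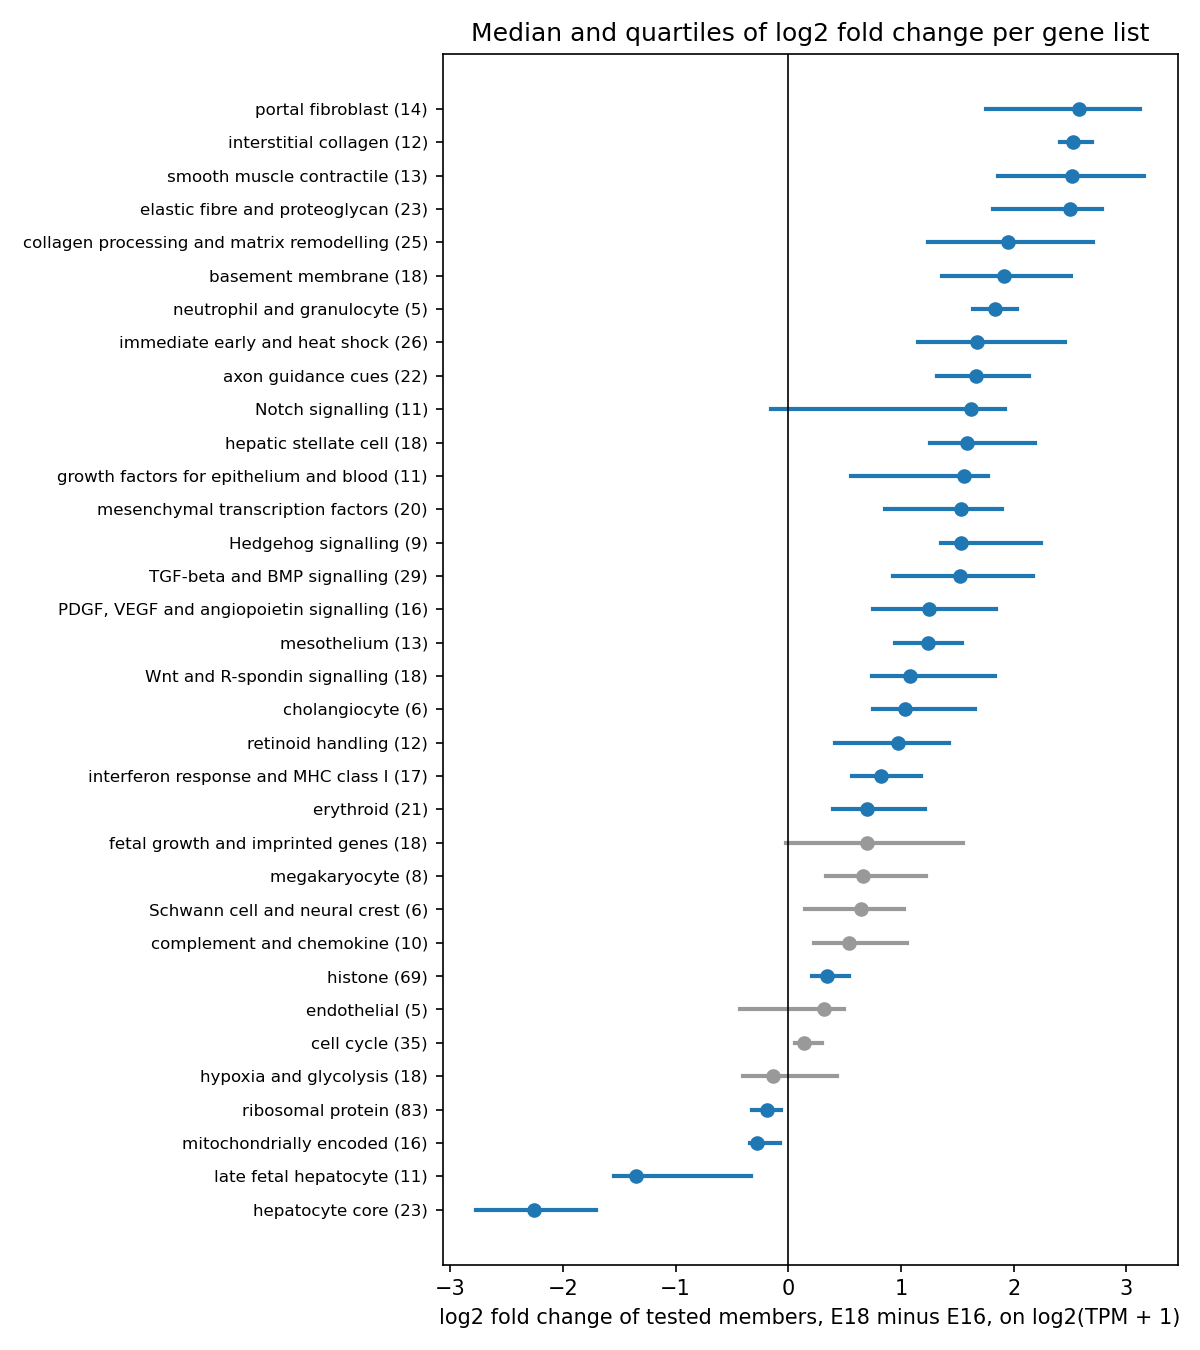
Median (point) and quartiles (bar) of the log2 fold change, E18 minus E16 on log2(TPM + 1), over the tested members of each of 34 lists, with the number of members in brackets. Blue lists passed camera with the preset correlation, 27 of 34; with an estimated correlation 0 passed. The hepatocyte core median lies at −2.26 and the interstitial collagen median at 2.52.

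Over all lists, camera with the preset correlation called 27 of 34, 23 higher and 4 lower at E18. With an estimated correlation it called 0, the smallest adjusted p was 0.314 and 0 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance to 1 side, called 21. Lists called by camera but not by fry were growth factors (fry adjusted p = 0.0529), retinoid handling (0.0801) and late fetal hepatocyte (0.226). Histone (0.160), mitochondrially encoded (0.174) and ribosomal protein genes (0.410) were the others. On ranks, camera did not call the Notch list (adjusted p = 0.0799). Several genes sit in more than 1 list.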

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

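The tests with voom, thinned reads, the collagen score, both B libraries left out and Gm26917 left out were chosen after the result was seen; the others were planned. Against 618 calls (549 higher, 69 lower), limma called 347 (305 and 42) with a pseudocount of 5, 406 (360 higher) with TPM of at least 5 in 3 libraries, 399 (314 higher) with quantile normalization and 18 (15 and 3) at a minimum fold of 1.5. It called 1035 (881 and 154) when rescaled without mitochondrial and small RNA genes, 1069 (251 lower) when Gm26917 was left out too, 4316 (2795 and 1521) with array weights and 1448 (1277 and 171) with voom, while median-of-ratios scaling gave 107 lower. It called 0 (0 higher, 0 lower) with no filter, with the hepatocyte score, with the collagen score and without both B libraries, where 4571, 1766, 668 and 2846 genes had an unadjusted p under 0.05. Leaving out 1 library gave 0 to 664 calls (0 to 531 higher, 0 to 133 lower), with 2765 to 4352 genes at an unadjusted p under 0.05; in these fits fewer samples remain. The collagen score averages 12 genes that were themselves called, so its fit cannot separate a common share from other causes. The hepatocyte score averages the 23 hepatocyte core genes, Alb and Ahsg among them. It ran from 4.99 to 6.91 at E16 and from 2.79 to 3.93 at E18, so its fit has the same limit. Voom shared 557 and thinned reads 543 of the 618 genes, and no called gene changed sign outside the collagen score, where 162 did. The cause of these changes in the call count was not tested. All fits without 1 library had the same number of libraries and gave 0 to 664 calls, so sample number alone does not account for the spread among them. Whether fewer libraries account for the fits with 0 calls cannot be told.

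With the letter as a replicate block the count was 0 (0 higher, 0 lower), with 3195 genes at an unadjusted p under 0.05, and 28 lists passed. The labels do not say what the letters mark. Correlations of same-letter deviations from the day means were 0.10 for A, the highest of its comparisons, −0.14 for B and −0.12 for C, and B and C correlated better with other letters; this shows no consistent pairing and does not exclude a shared batch.

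The difference between mean correlations within and between days was 0.0444; it was 0.0241 with no filter and 0.0653 with TPM of at least 5 in 3 libraries, and ranged from 0.0312 to 0.0637 when 1 library was left out. Lists past the threshold, 27 at first, were 0 with an estimated correlation, 6 with the collagen score and 23 to 28 when 1 library was left out. For single lists, 794 of the values under alternatives kept direction and side, 61 lost the call and 19 gained it. For single genes these were 1217, 706 and 30.

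Directions reversed as follows, and the cause was not tested. The endothelial list turned to higher with no filter (adjusted p = 0.0570), a mean TPM of at least 1 (0.532), median-of-ratios scaling (0.957), fry (0.458), camera on ranks (0.932), and without E16 replicate C (0.981) or E18 replicate C (0.831), in a range from 0.509 when 1 library was left out. The hypoxia and glycolysis list did so with fry (0.602), the hepatocyte score (0.287), the collagen score (0.543), and without E16 replicate B (0.948, in a range from 0.176 when 1 library was left out) or both B libraries (0.682). With the hepatocyte score, late fetal hepatocyte (0.334) and ribosomal protein (0.528) turned to higher. Alb and Ahsg, which are part of that score, were then at 0.32 and 1.54, and Cd68 was at −0.34. With the collagen score, ribosomal protein (3.7e-06) and mitochondrially encoded genes (0.140) turned to higher. These lists turned to lower with it: Hedgehog 0.0823, Notch 0.342, PDGF, VEGF and angiopoietin 0.251, Schwann cell 0.0745, TGF-beta and BMP 0.0843, Wnt 0.257, axon guidance 0.0863, basement membrane 0.316, cholangiocyte 0.509, collagen processing 0.284, complement and chemokine 0.0605, elastic fibre 0.316, imprinted genes 0.000116, growth factors 0.0125, stellate cell 0.000308, immediate early 0.0585, mesenchymal transcription factors 0.139 and retinoid handling 0.0605. Its log2 fold changes were Col1a1 −0.32, Klf4 −0.013, Cd68 −1.34, Lama2 −0.017, Unc5b −0.066, Meg3 −0.15, Pdgfrb −1.05, Col3a1 −0.63, Des −0.57, Jag1 −1.09, Pdgfra −0.25, Mki67 −0.10, Bgn −0.14, Col4a2 −0.20, Sfrp1 −0.58, Notch3 −0.34, Tcf21 −0.60, Gli2 −0.29, Igf2 −1.30 and Cxcl12 −0.71. At 4.41 to 6.83 reads per TPM and kb, genes near 1 TPM cannot show small changes.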

Other observations

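All tests below except those of overlapping gene models were chosen after the result was seen. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many as 618 genes, the real one, and the highest of the others gave 1 gene; for lists the real split gave 27 and 1 of the 10 splits gave as many, while the highest of the others gave 23. With 10 splits the share cannot fall under 0.05.

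Matrix and mesenchymal genes rose together, and a candidate explanation is that a larger share of the RNA came from mesenchymal cells at E18, raising all such genes by 1 common factor. Against that as the whole cause, 7 of 86 members, or 8.14%, rose more than the mean of 12 interstitial collagens. The 86 had a mean of at least 5 TPM and came from 6 matrix and mesenchymal lists beside the collagens. Limma was run on the difference, adjusted over members. Eln led, rising 1.60 ± 0.18 log2 units more (SE, n = 3 each). For 32 members the fold lay below the collagen mean. Among these, Plod3, Col18a1 and Angptl6 had negative log2 fold changes (−0.42, −0.42 and −0.043). Expression in cells whose share did not grow can lower a fold, but not raise it above the collagens unless it also lowers theirs. Cells whose share grew more than that of collagen-producing cells could raise a fold above the collagens, which was not tested. Read number alone is argued against, since after thinning, 93.1% of 72 called members of all 7 lists, collagens included, stayed called. Every E16 library was deeper than any E18 library, so thinning cannot separate the stage from other differences between libraries that go with depth. Scaling by a few abundant RNAs would move most genes, yet the median over all genes was 0.07 against 2.52 for the collagens. A common rise in mesenchymal share beneath gene-specific changes, unequal shifts in share among cell types, and a change with the stage within the cells stay open and untested.

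Hepatocyte genes fell together, which may reflect less hepatocyte RNA carried through the sort at E18. A single common factor is argued against: 41.2% of 34 members of both hepatocyte lists, and 39.1% of 23 core members alone, differed from the mean of the other members. Since log2(TPM + 1) shrinks the folds of low genes, the test was repeated with a pseudocount of 0.1 on members with a mean of at least 5 TPM: 15 of 29 members of both lists (51.7%) and 10 of 22 core members (45.5%) differed. Afp fell 1.29 ± 0.23 log2 units more than the rest of the core, and Ahsg 1.31 ± 0.19 less. Some members are also made by other cells, and hepatocytes change with the stage, so a lower share together with such changes stays open. The sort for eYFP should remove hepatocytes, and Alb was still at 521 ± 223 TPM at E18.

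Tagln stayed at 0.606 to 3.37 TPM while Acta2 reached 219 TPM in cells marked through the Tagln promoter. Reads that fall where gene models overlap may have been left out of its count, since 67.9% of its exon length lies under opposite-strand exons. The test set ribosomal protein, cell cycle and glycolysis genes with at least 50% of such overlap against those under 10%: median log2(TPM + 1) was 1.51 lower (a difference of −1.51, the same for overlap on either strand and on the opposite strand), but only 2 genes had such overlap, against 117 and 127 without, and they disagree: Rpl35, with 66.2% under opposite-strand exons, had a mean log2(TPM + 1) of 7.91, above the median of 7.27 of genes with little overlap, and Rpl23a one of 3.61. With 2 such genes loss of reads and low transcription at the time of sorting cannot be told apart.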
